A study of Oryza sativa with 8 samples.

How the data were processed

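The series measured transcripts by single-end RNA sequencing of total RNA from rice (Oryza sativa) shoot apical meristem, the tissue named by the labels. Per the labels, 2 libraries came from the cultivar Nipponbare, 3 from GW6a-4.6 and 3 from OsglHAT1-OE. GW6a-4.6 is a chromosome segment substitution line that carries a fragment of the Kasalath genome in a Nipponbare background. OsglHAT1-OE denotes transgenic plants in the Nipponbare background. Nothing in the labels says whether replicates were separate plants, and no batch, growth stage or sampling time was given. Per the submitters' processing notes, Bowtie, edgeR and the genome build IRGSP-1.0 were used, without versions or roles.

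The deposited values are a signal per transcript model, called RPM per the file headers and name. Every value of a library was a whole multiple of the worth of 1 read, within a tolerance of 0.01, so whole reads were recovered. The deposited signal therefore equals read alignments divided by a library total of 5207710 to 7667853 and scaled as for RPM. The columns summed to 2411271 to 2690367, so the values are not RPM in the strict sense. A read counted at each transcript model it aligned to would give such sums, though the alignments themselves were not examined. Near-identical paralogs and isoforms would then share reads. The recovered alignments per library are given with the results, and nothing distinguishes duplicate reads. Intervals and detection floors below cover counting error only.

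For each locus the transcript model with the highest mean was kept, which left 36819 loci of 43481 models. Loci with a value of 1 or more in at least 2 libraries were tested, 31487 in all. The main test was limma 3.58.1 (lmFit and eBayes with a trended prior) in R 4.3.3 on log2 of the deposited value plus 1. All 8 libraries entered 1 model with a mean per group, and the 3 pairwise contrasts were adjusted by Benjamini-Hochberg at 0.05. Folds printed in the text are ratios of group means. Log2 changes are from the model and understate the fold of genes near the floor. Against a group with no reads, the fold is a lower bound computed with 3 reads over the whole group. With 1 to 3 reads, the ratio is given with an exact binomial 95% counting interval. A test of the GW6a/OsglHAT1 transcript by exact permutation of libraries, two-sided, stood beside the model. The planned test had assumed RPM, and it was kept without further scaling between libraries. The median-ratio factors of the deposited values ran from 0.864 to 1.07, so scaling was examined among the alternatives.

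The groups, the 3 contrasts, the tests, the rule for naming genes and 20 gene lists were chosen before the data were examined. The rule took the GW6a/OsglHAT1 gene and the 10 annotated genes with the largest rise and the 10 with the largest fall in each line against Nipponbare. It also took 10 genes shared by both lines, 5 each way between the lines, and up to 4 members of each list with the smallest adjusted p. Genes taken for the size of their change, or as shared, also had to show no overlap between the libraries compared. Genes named outside this rule are marked as chosen after their values were seen. An early version of the annotation filter ignored capital letters and dropped some informative names; it was corrected after the first names had been seen. The lists were cytosolic ribosomal proteins, core histones, histone acetyltransferases and deacetylases, photosynthesis, cell cycle and DNA replication, cell wall expansion, auxin, cytokinin, gibberellin, MADS-box, heat shock proteins and factors, defence, lignin and secondary wall, root and nutrient uptake, seed storage, pollen and tapetum, transposon-like, grain size and yield genes, flowering time and circadian clock, and shoot meristem and inflorescence regulators. Most were matched to annotation text and the last 3 to locus identifiers. Another 4 lists were added after the data had been seen, namely late embryogenesis abundant (LEA), dehydrin and early light-inducible proteins, class III chitinases and glycoside hydrolase family 18, hAT-dimerisation domain loci, and sucrose and starch breakdown. The fixed pattern for acetyltransferases also matched transposons of the hAT family, so its counts are given with and without them. Counts of that list without hAT transposons also leave out RNA-processing proteins with a HAT helix domain, which the pattern matched too.

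Lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares the members of a list with the other loci, while fry tests the members against no change. The 2 therefore answer different questions. Their p-values were adjusted over all 60 combinations of list and contrast. Counts of members are given over all loci and adjusted over the list alone. Overlap of the lines was set beside 100 simulations of unchanged groups that shared the same Nipponbare libraries. Positions were examined by Fisher's exact test for chromosome 6 and for windows of 100 tested loci in identifier order. The planned windows of 2 Mb were replaced because the coordinates of the authors' build were not at hand, and no coordinates are printed. Of the steps for many genes, the limma contrasts and camera at the preset correlation were tested on simulated data first. Among 200 changed genes in simulated counts for GW6a-4.6 against Nipponbare (30951 genes), the test recovered 80% of the 2-fold and 97% of the 4-fold changes with 11 false calls. For OsglHAT1-OE against Nipponbare (30965 genes) it recovered 76% and 94% with 10 false calls, and for the 2 lines (30947 genes) 85% and 100% with 13. In that order, false calls made up 5.85%, 5.56% and 6.57% of all calls. The simulation held no scaling difference between libraries and far fewer changed genes than were called in the data.

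Alternatives covered the pseudocount (0.25), the filter (none, or 5), median-ratio scaling, quantile normalization, the libraries in the model, a replicate block, the prior without trend, and each library left out in turn. Added after the data had been seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, other choices of transcript model, and removal of loci with near-equal reads in every library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No value column of the table was left out. Raw reads were not analysed here.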

Results

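Transcripts were measured in the shoot apical meristem of rice, the dome of dividing cells that forms the leaves and later the panicle. By their labels, 2 libraries came from the cultivar Nipponbare, 3 from the substitution line GW6a-4.6 and 3 from OsglHAT1-OE transgenic plants. GW6a and OsglHAT1 are names of the same gene, which encodes an acetyltransferase that acts on histone H4, and both lines address what that gene does to meristem transcripts. The library totals behind the values were 6836650 and 5207710 reads for Nipponbare. They were 5602109, 5231450 and 5521707 for GW6a-4.6 and 6813185, 7667853 and 6783985 for OsglHAT1-OE. Counted at every transcript model, 13884868 to 20629337 alignments stood behind each library, and 3 reads corresponded to a value of 0.391 to 0.576. Correlations across genes of log2 values were 0.985 to 0.991 within groups and 0.955 to 0.958 between the lines. Between Nipponbare and either line they were 0.897 to 0.913. The first principal component, 57.6% of the variance, parted Nipponbare from both lines, and the second, 27.6%, parted the lines from each other. Replicates varied more than counting alone allows, with a chi-square per degree of freedom of 2.12 to 4.12. Replicate 3 of OsglHAT1-OE stood apart from its group on the second component (58.26 against 43.91 and 42.99), with 2.41 alignments per read against 2.66 to 2.69 in the other libraries and a median-ratio factor of 0.864 against 1.01 to 1.07.

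The GW6a/OsglHAT1 transcript, Os06t0650300-00, annotated as a GCN5-related N-acetyltransferase on chromosome 6, was examined first because it checks the labels. Its value was 1.88 ± 0.595 (SD, n = 2) in the libraries labelled Nipponbare, from 10 and 12 reads. The libraries labelled GW6a-4.6 held 2640, 2570 and 2910, a mean of 2710 ± 179 (n = 3) and 1440-fold above Nipponbare. Those labelled OsglHAT1-OE held 13.2, 8.87 and 10.02, a mean of 10.7 ± 2.25 (n = 3) from 90, 68 and 68 reads, 5.68-fold above Nipponbare. The overexpression label thus went with the smaller rise, and the libraries labelled GW6a-4.6 exceeded those labelled OsglHAT1-OE 253-fold. The log2 changes were 9.89 (SE 0.14, adjusted p = 7.7e-37), 2.02 (SE 0.14, adjusted p = 3.77e-15) and, between the lines, -7.87 (SE 0.12, adjusted p = 2.12e-34). Every library of each line lay above both Nipponbare libraries. The two-sided exact permutation p was 0.1 for each pair of groups, the smallest that 2 against 3 or 3 against 3 libraries can give. Because this transcript goes against the labels, groups are called by their labels throughout, and no direction below is tied to the dose of the gene.

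**Figure D1:**
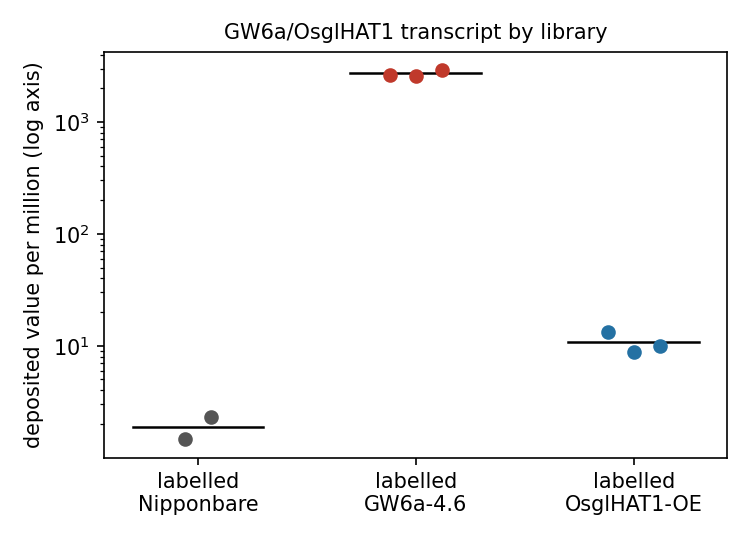
Deposited value of Os06t0650300-00 per library on a log axis, with points for libraries and lines for group means. The libraries labelled GW6a-4.6 lie at 2570 to 2910, those labelled OsglHAT1-OE at 8.87 to 13.2 and those labelled Nipponbare at 1.46 and 2.30.

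In the libraries labelled GW6a-4.6, set against Nipponbare to find what the substituted segment goes with, more core histone, cell cycle, wall expansion and auxin loci rose than fell, and more heat shock loci fell than rose. The list tests behind these groups passed at a preset correlation and were lost with an estimated one (adjusted p = 0.735 for each). The histone H2B.2 transcript Os08t0490900-00 rose from 76.2 ± 11 (n = 2) to 373 ± 30 (n = 3), 4.89-fold. Cyclin-A3-1 (Os03t0607600-00) rose 5.56-fold to 42.3 ± 3.5, and the beta-expansin Os10t0555900-02, of a family that loosens cell walls, rose 6.3-fold to 226 ± 9.4. The ribonuclease T2 transcript Os09t0537700-02 fell from 12500 ± 180 to 22.5 ± 1.3, which was 558-fold. The early light-inducible protein Os01t0246400-01, a chlorophyll-binding stress protein, fell 94.1-fold to 3.11 ± 0.39.

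Among the genes with the largest rises, all 3 libraries lay above both of Nipponbare because the naming rule required it. They included a subtilisin-like protease (Os10t0451900-01, 2.85 ± 1.1 to 431 ± 27, 151-fold) and a cinnamoyl-CoA reductase of lignin synthesis (Os02t0811800-01, 1.26 ± 0.7 to 249 ± 5.7, 197-fold). An alpha-amylase, which breaks down starch (Os02t0765600-01), rose 83.3-fold to 178 ± 19. A terpenoid synthase (Os04t0340300-01) rose 53.9-fold to 393 ± 19. A transferase (Os12t0459100-00) had no reads in Nipponbare and 73.5 ± 5 here, at least 295-fold higher. Among the largest falls, the ABA-induced membrane protein PM 19 (Os05t0381400-01) went from 136 ± 3.3 to 0.183 ± 0.18 from 3 reads, a ratio of 0.00134 with a counting interval of 0.000277 to 0.00393. A seed maturation protein (Os06t0341300-01) fell from 93 ± 12 to no reads, at least 507-fold lower. The dehydrin RAB 16C (Os11t0454000-01), a desiccation protein, fell 86.3-fold to 2.02 ± 0.25.

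Of 55 core histone loci, 48 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 1.46 (camera adjusted p = 7.12e-17). That call was lost with adjusted p = 0.735 with an estimated correlation, as were all list calls below, and histone paralogs may share reads. List calls are those of camera at the preset correlation unless fry is named, and ranges of adjusted p cover the 18 alternatives that kept that test. Of 48 cell cycle and replication loci, 33 rose and 1 fell (35 and 2 adjusted over the list alone, median 0.72, adjusted p = 3.55e-07, and adjusted p = 0.735 with an estimated correlation). The replication licensing factor MCM3 (Os05t0476200-01) rose 2.53-fold to 166 ± 14 and the sliding clamp PCNA (Os02t0805200-01) 2.22-fold to 271 ± 11. Of 45 wall expansion loci, 30 rose and 2 fell (32 and 3 adjusted over the list alone, median 1.15, adjusted p = 5.75e-07, and adjusted p = 0.735 with an estimated correlation). The alpha-expansin OsEXPA4 (Os05t0477600-01) rose 6.85-fold to 122 ± 10. Of 99 auxin loci, 66 rose and 6 fell (72 and 6 adjusted over the list alone, median 0.78, adjusted p = 1.06e-08, and adjusted p = 0.735 with an estimated correlation). The auxin response factor Os02t0141100-00 rose 5.25-fold to 390 ± 22 and the auxin-conjugating GH3 enzyme Os01t0785400-01 rose 11.9-fold to 95.5 ± 3.9.

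Meristem and inflorescence regulators also rose, 12 of 18 with 2 falling (12 and 2 adjusted over the list alone, median 1.01, adjusted p = 0.0134, and adjusted p = 0.768 with an estimated correlation). The call was lost with a filter at 5 (0.0566, in a range of 0.00805 to 0.0566). The homeobox genes OSH1 (Os03t0727000-01), which maintains the meristem, and OSH15 (Os07t0129700-01) rose 3.1-fold to 98 ± 10 and 3.46-fold to 169 ± 16. Of 23 grain size and yield genes, the GW6a gene included, 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.4, adjusted p = 0.0171, and adjusted p = 0.857 with an estimated correlation). The GW6a gene entered at a log2 change of 9.89, and no list test without it is given. The cell wall invertase GIF1 (Os04t0413500-01), which feeds the filling grain, rose 32-fold from 3 ± 0.1 to 96.1 ± 11, and the brassinosteroid synthesis gene D2 (Os01t0197100-00) rose 7.43-fold to 35.3 ± 3. FLO2 (Os04t0645100-02) fell 3.95-fold to 170 ± 7.4. The cytokinin-degrading enzyme Gn1a/OsCKX2 (Os01t0197700-01) fell 9.5-fold to 1.08 ± 1.2.

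Heat shock loci fell more often than they rose, 70 against 19 of 152 (71 and 19 adjusted over the list alone, median -0.28, adjusted p = 2.35e-07, and adjusted p = 0.735 with an estimated correlation). An Hsp70 (Os03t0276500-01) fell 3.86-fold from 1600 ± 71 to 414 ± 7.2, and the Hsp82 locus Os08t0500700-01 fell 2.7-fold to 579 ± 9.8. Root and nutrient uptake loci fell 10 times and rose 3 times among 21 (11 and 3 adjusted over the list alone, median -0.48, adjusted p = 0.00677, and adjusted p = 0.852 with an estimated correlation), as for an ammonium transporter (Os03t0838400-01) at 51.2 ± 1.8 and 18.5 ± 2.1. Lignin loci rose 19 times and fell 6 times among 44 (19 and 7 adjusted over the list alone, median 0.29, adjusted p = 0.0212, and adjusted p = 0.857 with an estimated correlation). Defence loci rose 75 times and fell 31 times among 178 (75 and 34 adjusted over the list alone, median 0.28, adjusted p = 0.0472, and adjusted p = 0.857 with an estimated correlation). The class III chitinase homologue Chib3H-b (Os11t0700900-02), which cuts fungal cell walls, rose 17.6-fold to 386 ± 30. The defence call was lost under 8 of the 18 alternatives, with adjusted p of 0.056 to 0.0789, among them those without Nipponbare replicate 2, without GW6a-4.6 replicate 1 and without OsglHAT1-OE replicate 3.

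The other lists were not called against Nipponbare by camera in these libraries, while fry called cytokinin (adjusted p = 0.0162) and acetyltransferases and deacetylases with hAT transposons included (adjusted p = 0.000784), both as higher. Photosynthesis loci, a leaf marker, rose 11 times and fell 12 times among 57 (11 and 12 adjusted over the list alone, adjusted p = 0.157, with 0.0494 for a filter at 5 and a range of 0.0494 to 0.457 by camera). A RuBisCO small subunit (Os12t0292400-01) fell 5.01-fold to 59.5 ± 2.9, while photosystem I subunit N (Os12t0189400-01) rose 2.86-fold to 56.3 ± 7.3. Ribosomal protein loci rose 32 times and fell 22 times among 176 (31 and 20 adjusted over the list alone, adjusted p = 0.649), and their median turned from 0.02 to -0.06 under median-ratio scaling. Cytokinin loci rose 5 times and fell once among 14 (adjusted p = 0.36), gibberellin loci 6 and 10 times among 22 (adjusted p = 0.184) and MADS-box loci 4 and 8 times among 22 (adjusted p = 0.13). Seed storage loci rose 2 and fell 3 times among 13 (adjusted p = 0.593), pollen and tapetum loci 16 and 4 times among 49 (adjusted p = 0.182) and flowering and clock loci 4 and 5 times among 16 (adjusted p = 0.574). Transposon-like loci rose 21 and fell 15 times among 74 (adjusted p = 0.961). The fixed list of histone acetyltransferases and deacetylases rose 13 and fell 10 times among 47 (adjusted p = 0.364), and 3 and 2 times among the 17 left without hAT transposons. From the cytokinin list on, these counts were the same adjusted over the list alone.

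In all, 14566 of 31487 tested loci (46.3%) differed between the libraries labelled GW6a-4.6 and Nipponbare, 5329 of them by a model log2 change of at least 1. Of the 14566 loci, 8413 were higher and 6153 lower. That split rested on the scaling, being 7992 and 7901 under median-ratio scaling and 7964 and 7958 under quantile normalization. By edgeR it was 8063 and 7598, and by DESeq2 7100 and 6945. The groups did not overlap at 20309 loci (64.5%, where chance gives 20%).

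In the libraries labelled OsglHAT1-OE, set against Nipponbare to find what the transgene goes with, more core histone, cell cycle, wall expansion and auxin loci again rose than fell. These list calls too were lost with an estimated correlation (adjusted p = 0.735 for each). Histone H2B.2 (Os08t0490900-00) rose 7.06-fold to 538 ± 55 (n = 3), the alpha-expansin OsEXPA4 (Os05t0477600-01) 12.5-fold to 223 ± 24 and cyclin-A3-1 (Os03t0607600-00) 6.79-fold to 51.7 ± 6.1. The invertase GIF1 (Os04t0413500-01) rose 36.2-fold to 109 ± 15. The early light-inducible protein Os01t0246400-01 fell 260-fold to 1.13 ± 0.51, and a WRKY transcription factor of defence signalling (Os02t0181300-01) fell 10.7-fold from 72.3 ± 5 to 6.78 ± 1.6.

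For other large rises, too, the naming rule required all 3 libraries to lie above both of Nipponbare. A polygalacturonase beta subunit (Os10t0409400-01) was at 0.146 ± 0.21 from 2 reads in Nipponbare and 58.1 ± 0.78 here, a ratio of 397 with a counting interval of 96.7 to 2890. A terpenoid synthase (Os03t0347900-01) rose 62.9-fold to 79 ± 6.2 and a cytochrome P450 of the CYP78A family (Os08t0547300-01) 25.7-fold to 154 ± 18. The dehydrin RAB 16B (Os11t0454200-01) fell 112-fold from 342 ± 20 to 3.06 ± 1.1, a metallothionein (Os12t0570700-01) 106-fold from 728 ± 18 to 6.85 ± 0.77, and the seed maturation protein Os06t0341300-01 fell to no reads, at least 660-fold lower.

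Core histones rose at 51 of 55 loci and fell at 1, with the same counts adjusted over the list alone (median log2 change 1.88, or 1.9 with genes near the floor at their bounds, adjusted p = 5.79e-24, and adjusted p = 0.735 with an estimated correlation). Cell cycle loci rose 29 times and fell 4 times, likewise when adjusted over the list alone (median 0.64, adjusted p = 5.75e-07, and adjusted p = 0.735 with an estimated correlation). Wall expansion loci rose 32 times and fell 6 times (33 and 6 adjusted over the list alone, median 1.02, or 1.06 with such bounds, adjusted p = 5.31e-09, and adjusted p = 0.735 with an estimated correlation). Auxin loci rose 61 times and fell 6 times, likewise when adjusted over the list alone (median 0.73, adjusted p = 1.04e-09, and adjusted p = 0.735 with an estimated correlation). The GH3.5-like enzyme Os05t0500900-01 rose 14.9-fold from 5.44 ± 0.45 to 81.2 ± 7.2. Meristem regulators rose 12 times and fell 2 times, OSH1 (Os03t0727000-01) rising 3.33-fold to 106 ± 8.7 (12 and 2 adjusted over the list alone, median 0.85, adjusted p = 0.00383, and adjusted p = 0.735 with an estimated correlation). Grain size genes rose 15 times and fell 2 times (15 and 4 adjusted over the list alone, median 0.71, adjusted p = 0.000164, and adjusted p = 0.852 with an estimated correlation), and GL7 (Os07t0603300-01) rose 2.24-fold to 326 ± 14. The GW6a gene is again a member, at a log2 change of 2.02.

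Ribosomal protein loci rose 87 times and fell 16 times (92 and 16 adjusted over the list alone, median 0.19, adjusted p = 0.00185, lost by fry at 0.289, and adjusted p = 0.857 with an estimated correlation), with RPL38 (Os11t0433900-01) 1.55-fold higher at 564 ± 32. Without OsglHAT1-OE replicate 3, the library with fewer alignments per read, these counts were 110 and 13. Pollen and tapetum loci rose 19 times and fell 5 times, likewise when adjusted over the list alone (median 0.27, adjusted p = 0.0248, lost by fry at 0.0936, and adjusted p = 0.857 with an estimated correlation), as for an Ole e 1 allergen (Os07t0674400-01) at 33.7 ± 2.9 and 118 ± 21. Heat shock loci fell 80 times and rose 19 times, likewise when adjusted over the list alone (median -0.32, adjusted p = 0.00023, and adjusted p = 0.857 with an estimated correlation), and the Hsp70 locus Os03t0276500-01 fell 5.87-fold to 272 ± 14. Defence loci fell 80 times and rose 39 times (80 and 41 adjusted over the list alone, median -0.38), and the list was not called by camera (adjusted p = 0.0766). It was called by fry (0.0127), with a filter at 5 (0.0336), under median-ratio scaling (0.0464) and without Nipponbare replicate 2 (0.0377), and its adjusted p by camera ranged from 0.0336 to 0.13. Root and nutrient uptake loci fell 12 times and rose 4 times, likewise when adjusted over the list alone (median -0.74, adjusted p = 0.0793, with 0.00297 by fry, 0.0477 without Nipponbare replicate 2 and a range of 0.0477 to 0.144 by camera).

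Photosynthesis loci rose 11 and fell 11 times (11 and 10 adjusted over the list alone, adjusted p = 0.86), and lignin loci rose 12 and fell 12 times (12 and 13 adjusted over the list alone, adjusted p = 0.91). MADS-box loci rose 2 and fell 10 times (3 and 10 adjusted over the list alone, adjusted p = 0.2, called by fry at 0.0112), as for the floral gene SPW1 (Os06t0712700-01) at 38.4 ± 3.2 and 15.8 ± 2.5. Gibberellin loci rose 6 and fell 8 times (7 and 11 adjusted over the list alone, adjusted p = 0.69), cytokinin loci 5 and 2 times (adjusted p = 0.283, called by fry at 0.029), flowering and clock loci 6 and 6 times (adjusted p = 0.682) and transposon-like loci 21 and 19 times (adjusted p = 0.434). For these 3 lists the counts were the same adjusted over the list alone. Seed storage loci rose once and fell 4 times (1 and 3 adjusted over the list alone, adjusted p = 0.795). The acetyltransferase and deacetylase list rose 4 and fell 10 times (adjusted p = 0.595), or 3 and 5 times without hAT transposons, in each case likewise when adjusted over the list alone. In it the type B histone acetyltransferase Os09t0347800-01 rose 1.95-fold to 76.8 ± 5.6 and a histone deacetylase (Os02t0215200-02) fell 3.82-fold to 8.91 ± 1.4.

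In all, 16536 loci (52.5%) differed between the libraries labelled OsglHAT1-OE and Nipponbare, 6709 of them by a model log2 change of at least 1. Of the 16536 loci, 7179 were higher and 9357 lower. This split too rested on the scaling, being 8689 and 8923 under median-ratio scaling and 9120 and 8261 under quantile normalization. By edgeR it was 8952 and 8692, and by DESeq2 7951 and 8089. The groups did not overlap at 21055 loci (66.9%, where chance gives 20%).

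**Figure D2:**
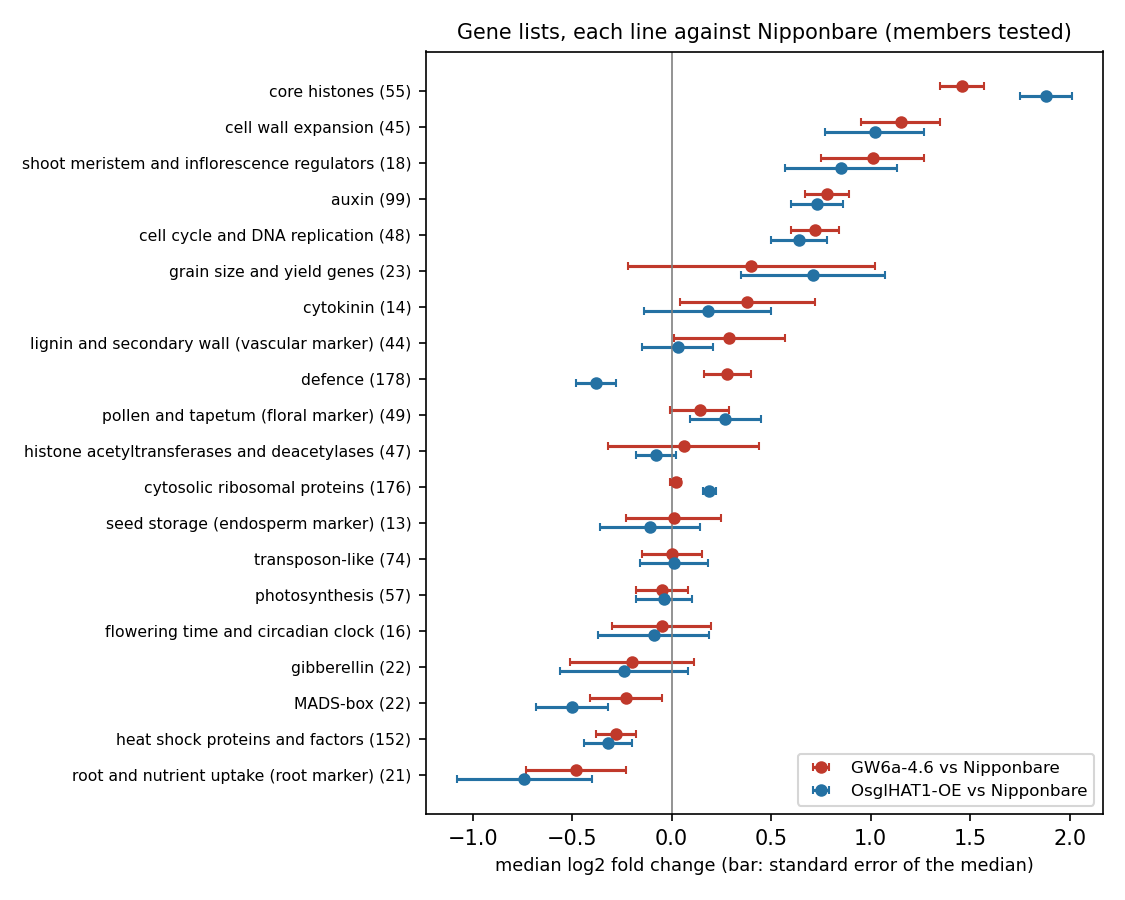
Median log2 fold change of the members of 20 gene lists for each line against Nipponbare, with bars for the standard error of the median and the number of members in parentheses. The bars come from the spread among members, which are not independent, and do not measure variation between libraries. Core histones lie at 1.46 and 1.88 and defence at 0.28 and -0.38, for GW6a-4.6 and OsglHAT1-OE by label.

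Both lines were compared for a shared response, since both are meant to alter the same gene. The LEA protein Os03t0168100-01 fell in both, from 113 ± 15 in Nipponbare to 0.365 ± 0.36 and 0.0491 ± 0.085 in the libraries labelled GW6a-4.6 and OsglHAT1-OE. The ribonuclease T2 transcript Os09t0537700-02 fell 558-fold and 78.7-fold, the achaete-scute-related transcription factor Os01t0952800-01 71-fold and 143-fold, and the UFG2-like transcript Os03t0723400-01 526-fold and 96.9-fold. The transferase Os12t0459100-00, without reads in Nipponbare, was at 73.5 ± 5 and 83.8 ± 9.6. The clock gene PRR95 (Os09t0532400-01) rose 3.93-fold to 453 ± 22 and 5.44-fold to 628 ± 26. The transposase Os07t0414900-02 rose 58.6-fold to 41.2 ± 3.8 and 37.5-fold to 26.4 ± 4.5.

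Past the threshold in both lines with 1 sign were 10828 loci, 5585 higher and 5243 lower, where independent lists would share 3746. Simulated unchanged groups that shared the same Nipponbare libraries gave 0 by limma, and 524 on average at an unadjusted p under 0.05. By edgeR 11822 loci were shared and by DESeq2 10568. Across genes, which are not independent replicates, the log2 changes of the lines correlated with Pearson r = 0.80 and Spearman rho = 0.78. Shared controls alone gave 0.60 and 0.57 in simulation, and the covariance was 0.70 against 0.029. For these counts and correlations the 2 Nipponbare libraries were not divided between the contrasts, so their own deviation enters both.

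In opposite directions went 419 loci, 384 of them higher in the libraries labelled GW6a-4.6 and lower in those labelled OsglHAT1-OE. Among them, chosen after their values were seen, was the pathogenesis-related gene PR1 (Os07t0127700-01), at 7.46 ± 1.04 in Nipponbare, 64.4 ± 8.58 in GW6a-4.6 and 0.903 ± 0.813 in OsglHAT1-OE by label. The defence regulator WRKY62 (Os09t0417800-01), chosen likewise, was at 5.51, 50.5 ± 7.06 and 1.59. The count rested on the control libraries, being 203 without Nipponbare replicate 1 and 196 without Nipponbare replicate 2. Its split rested on the scaling, being 348 higher and 135 lower in GW6a-4.6 by label under median-ratio scaling, 330 and 91 under quantile normalization, 346 and 150 by edgeR, and 289 and 109 by DESeq2.

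**Figure D3:**
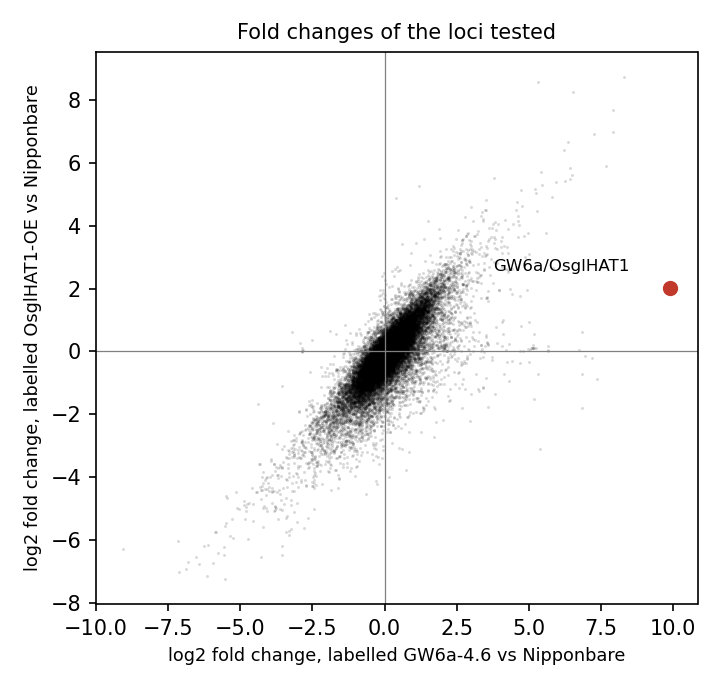
Log2 fold change of each tested locus against Nipponbare for the libraries labelled GW6a-4.6 (horizontal) and OsglHAT1-OE (vertical), with 1 point per locus and the GW6a/OsglHAT1 gene marked at 9.89 and 2.02. Pearson r across loci was 0.80.

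Set against each other, the lines differed in that more defence and lignin loci were lower than higher in the libraries labelled OsglHAT1-OE, and more core histone loci higher than lower. With an estimated correlation these list calls were lost (adjusted p = 0.735, 0.852 and 0.735). The class III chitinase Os11t0701400-01 was at 149 ± 15 (n = 3) in GW6a-4.6 by label and 0.468 ± 0.16 (n = 3) in OsglHAT1-OE, 318-fold lower. The PR-1a gene Os10t0191300-01 fell 7.45-fold from 445 ± 45 to 59.7 ± 7.9. The cinnamoyl-CoA reductase Os02t0811800-01 fell 104-fold to 2.4 ± 0.22, and a cinnamyl alcohol dehydrogenase (Os04t0612700-01) 25.5-fold from 201 ± 5.6 to 7.9 ± 3. Higher were ribonuclease T2 (Os09t0537700-02), 7.1-fold at 159 ± 16, and a lectin (Os04t0173800-01), 5.86-fold at 92.9 ± 20.

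Of the 178 defence loci, 98 fell and 11 rose (101 and 11 adjusted over the list alone, median -0.56, or -0.57 with genes near the floor at their bounds, adjusted p = 2.59e-09, and adjusted p = 0.735 with an estimated correlation). Of 44 lignin loci, 24 fell and 2 rose, likewise when adjusted over the list alone (median -0.43, adjusted p = 9.6e-05, and adjusted p = 0.852 with an estimated correlation). Core histones rose at 39 loci and fell at 1 (43 and 1 adjusted over the list alone, median 0.47, adjusted p = 3.19e-18, and adjusted p = 0.735 with an estimated correlation), with Os05t0438700-01 1.53-fold higher at 577 ± 51. Ribosomal protein loci rose 57 times and fell 11 times (62 and 11 adjusted over the list alone, median 0.13, adjusted p = 1.04e-09, lost by fry at 0.277, and adjusted p = 0.857 with an estimated correlation). Those counts were 103 and 9 without OsglHAT1-OE replicate 3. The grain size list includes the GW6a/OsglHAT1 gene, whose log2 change of -7.87 between the lines entered its mean and its tests. Grain size genes rose 7 times and fell 2 times, with a median of 0.17, a mean of -0.13 and a camera test in favour of higher values (adjusted p = 0.0046, lost by fry at 0.552, and adjusted p = 0.857 with an estimated correlation). Quantile normalization ended that call (0.056, in a range of 0.00106 to 0.056). The receptor BRI1 (Os01t0718300-01) rose 1.43-fold to 402 ± 9 and BG1 (Os03t0175800-01) 2.09-fold to 32.7 ± 3.8.

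Between the lines all loci had a median log2 change of -0.13, so camera, which compares with the other loci, can call a list near 0 higher. Such a call is relative to the other loci, and fry tests against no change. Auxin loci rose 17 and fell 17 times, with a median of -0.03 and a test in favour of higher values (adjusted p = 0.0396, lost by fry at 0.817, and adjusted p = 0.857 with an estimated correlation). That call was lost in 6 of the 18 alternatives, among them those without GW6a-4.6 replicate 2, without GW6a-4.6 replicate 3 and without OsglHAT1-OE replicate 3 (adjusted p of 0.052 to 0.203 over the 6). Wall expansion loci rose 8 and fell 4 times, with a median of 0.09 and a mean of -0.02 (adjusted p = 0.0166, lost by fry at 0.935 and without GW6a-4.6 replicate 2 at 0.0533, in a range of 0.00858 to 0.0533 by camera, and adjusted p = 0.857 with an estimated correlation). Photosynthesis loci rose 10 and fell 7 times, with a median of 0.03 and a mean of -0.05 (8 and 3 adjusted over the list alone, adjusted p = 0.0212, lost by fry at 0.827 and without GW6a-4.6 replicate 2 at 0.241, in a range of 0.00208 to 0.241 by camera, and adjusted p = 0.857 with an estimated correlation). Flowering and clock loci rose 4 and fell 3 times (adjusted p = 0.0267, and adjusted p = 0.857 with an estimated correlation), a call that was lost by fry (0.185), without GW6a-4.6 replicate 1 (0.0685), without OsglHAT1-OE replicate 3 (0.052) and under quantile normalization (0.303), in a range of 0.0171 to 0.303. Lists not called by camera were cell cycle (2 rose and 8 fell, or 1 and 7 adjusted over the list alone, adjusted p = 0.536), heat shock (18 and 31, 0.364, with a median that turned from -0.11 to 0.01 under median-ratio scaling) and acetyltransferases and deacetylases (2 and 15, 0.0958). The last was 1 and 5 among the 17 loci left without hAT transposons (0.362). It was called lower without GW6a-4.6 replicate 1 (0.0404) and by fry (0.000558, or 0.0138 without hAT transposons). The uncalled remainder (adjusted p of 0.146 to 0.992) rose and fell as follows: cytokinin 1 and 2, gibberellin 3 and 2, MADS-box 2 and 5, root 1 and 7, seed storage 1 and 3, pollen 8 and 8, transposon-like 9 and 16, and meristem regulators 2 and 3. Apart from gibberellin (2 and 2), the counts of this paragraph not given otherwise were the same adjusted over the list alone, as were those of grain size genes. The regulator OSH15 (Os07t0129700-01) fell 1.78-fold to 94.9 ± 12.

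In all, 10209 loci (32.4%) differed between the lines, 2422 higher and 7787 lower in OsglHAT1-OE by label, and 13435 (42.7%, where chance gives 10%) did not overlap. The median log2 change of all loci was -0.13 and moved to 0.01 under median-ratio scaling, which split the calls 5893 to 5857, so 23.7% of calls were higher as deposited and 50.2% after that scaling. Quantile normalization gave 6169 higher and 5190 lower, edgeR 6063 and 5854, DESeq2 5045 and 5107, and the deposited values without OsglHAT1-OE replicate 3 gave 3259 and 6111. The defence list kept more falls than rises, 89 to 16 under median-ratio scaling and 87 to 19 under quantile normalization. The alpha-tubulin SRS5 (Os11t0247300-01), higher by 0.33 on the log2 scale, was at -0.07 under quantile normalization.

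Positions were examined because a substitution line could carry donor genome beyond the intended segment. On chromosome 6, which bears GW6a, 44.6% of 2583 loci differed between the libraries labelled GW6a-4.6 and Nipponbare, against 46.4% elsewhere (odds ratio 0.93, 95% interval 0.857 to 1.01, two-sided Fisher exact p = 0.08). For the libraries labelled OsglHAT1-OE the shares were 51.5% and 52.6% (odds ratio 0.955, Fisher exact p = 0.258). The window of 100 loci that holds the GW6a gene had 52 called loci in the first contrast (adjusted p = 0.723) and 59 in the second. Past the adjusted threshold were 6 of 319 windows for GW6a-4.6, of which the chromosome 6 window from Os06t0605750-00 to Os06t0624750-00 held only 27 called loci (adjusted p = 0.018). A window of chromosome 7 from Os07t0669750-00 to Os07t0684500-01 held 73 (adjusted p = 2.82e-05), and the window of 56 loci at the end of chromosome 11 that starts at Os11t0696200-01, where many of the raised class III chitinases lie, held 40 (adjusted p = 0.0236). Those neighbouring paralogs may share reads, while the window test treats loci as independent. For OsglHAT1-OE, 0 of 319 windows passed by Fisher's exact test on the limma calls, and 34 had an unadjusted p under 0.05, beside 37 for GW6a-4.6. With windows of 250 loci, 3 of 132 passed for OsglHAT1-OE. Between the lines, 32.6% of chromosome 6 loci and 32.4% elsewhere differed (odds ratio 1.01, Fisher exact p = 0.809). There 1 of 319 windows passed, on chromosome 7 from Os07t0524200-01 to Os07t0543100-00 with 55 called loci (adjusted p = 0.00147), and 29 had an unadjusted p under 0.05. No window test was run on the edgeR or DESeq2 calls.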

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

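The tests of explanations in this part were chosen after the results had been seen, except the thinning of libraries and the splits of the 6 libraries. The contrasts, and the lists not marked as added, were planned.

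The GW6a/OsglHAT1 transcript differed between the lines against the direction of their labels, by a log2 change of -7.87 (adjusted p = 2.12e-34, all 3 libraries on each side). Reads of another annotated gene of near-identical sequence are argued against, because 0 other transcript models held near-equal counts in the same 3 libraries. An exchange of the 2 line labels stays open: of the 50 tested loci on either side of the gene, 11 departed from Nipponbare by 1 log2 unit or more in the libraries labelled OsglHAT1-OE alone and 2 in those labelled GW6a-4.6 alone, or 84.6% against 65.6% elsewhere. The odds ratio was 2.89 (95% interval 0.629 to 26.8, Fisher exact p = 0.241), which cannot be told apart from no enrichment, and a sign test (exact p = 0.0225) that ignored the genome-wide imbalance was replaced after its result had been seen. A strong effect of the donor allele on its own transcript, named by the design, might also give this level and was not tested.

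Nipponbare stood apart from both lines, with 10828 loci changed alike in both against 3746 for independent lists. A response in proportion to the GW6a/OsglHAT1 level is argued against as the account of the called genes as a whole. Over all 14565 other genes called in GW6a-4.6 the median signed ratio of log2 changes, OsglHAT1-OE to GW6a-4.6 by label, was 0.965 (quartiles 0.568 and 1.3), while that of the gene itself was 0.2. With the lines set against different Nipponbare libraries the median was 0.971, or 0.957 with those libraries exchanged. That test replaced one on genes called in both lines. It cannot decide on a dose-related part of the response, as 22% of the ratios were below 0.5. Any other difference of Nipponbare from both lines would also enter both changes and bring the ratio nearer to equal changes. Library size is argued against too, because 10527 loci were still shared after every library had been thinned to the smallest. A smaller share of leaf tissue in the lines could not be decided, since the photosynthesis list had a median log2 change of -0.05 with members going both ways (RuBisCO small subunit Os12t0292400-01 at 298 ± 1.2 and 59.5 ± 2.9), while 12 of 18 meristem regulators rose. A difference in stage, plants or sampling between the Nipponbare libraries and the rest, and a threshold response to the gene, may also account for it, and neither was tested.

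A group of 8 hAT transposon loci differed between the lines, being raised by at least 1 log2 unit in the libraries labelled GW6a-4.6 (means of 32.2 to 50.2) and lower in those labelled OsglHAT1-OE. Of all 26 tested hAT loci, 10 rose and 8 fell in GW6a-4.6 by label (median -0.01). Between the lines the whole list, added after seeing the data, was not called by camera (adjusted p = 0.0563, and adjusted p = 0.852 with an estimated correlation) and was called by fry (adjusted p = 0.000138). Reads of the 8 numbered 4680 in GW6a-4.6, 16 in OsglHAT1-OE and 0 in Nipponbare. A candidate explanation is 1 multi-copy element whose reads were counted at each copy, since the largest group mean was only 1.56 times the smallest. A single aberrant library is argued against, as the highest of the 3 libraries held 1.23 times the lowest. Copies carried by the substituted segment stay open as a biological source and were not tested.

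In opposite directions against Nipponbare went 419 loci that also differed between the lines, 384 of them higher in GW6a-4.6 by label. That split was 348 to 135 under median-ratio scaling, 330 to 91 under quantile normalization, 346 to 150 by edgeR and 289 to 109 by DESeq2. The number of such loci was 203 without Nipponbare replicate 1 and 196 without Nipponbare replicate 2, and 338 to 496 in the other alternatives. Defence loci differed between the lines by a median log2 change of -0.56 (adjusted p = 2.59e-09, and adjusted p = 0.735 with an estimated correlation; 98 of 178 loci lower). Class III chitinases and glycoside hydrolases of family 18, a list added after seeing the data, differed by -2.97 (adjusted p = 1.34e-12, and adjusted p = 0.69 with an estimated correlation, with 16 of 19 loci lower). Many of these loci are neighbouring paralogs that may share reads.

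Of the 10 splits of the 6 line libraries into 3 and 3, only 1, the real one, gave 10209 changed loci, and the highest of the others gave 0 by limma. At an unadjusted p under 0.05 these numbers were 12991 and 1319, and no other tool was run on the splits. With 10 splits the share is never under 0.1, so they are too few for a share under 0.05. Each of the other splits mixed both lines on either side, so the difference between the lines entered its spread. Low counts there were likely beforehand and do not measure what chance would give.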

How the results depend on the processing

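Added after the data had been seen were edgeR, DESeq2, the other transcript models, removal of 179 loci with near-equal reads, and windows of 50 and 250 loci. The planned windows of 1 and 5 Mb were not run for want of coordinates. The correlation of the lines and the 3 changes of the GW6a/OsglHAT1 transcript kept their direction and their side of the threshold in every alternative that was run. The split of calls between the lines did not: 2422 higher and 7787 lower became 5893 and 5857 under median-ratio scaling, 6169 and 5190 under quantile normalization, 6063 and 5854 by edgeR, and 5045 and 5107 by DESeq2. The splits of each line against Nipponbare also moved under those settings. Without 1 library at a time, the counts ranged from 10718 to 15798 for GW6a-4.6 against Nipponbare, 12779 to 16651 for OsglHAT1-OE against Nipponbare, 8193 to 9380 between the lines and 7943 to 11557 for both lines. The correlation ranged from 0.795 to 0.808, the log2 changes of the gene from 9.68 to 10.1, 1.81 to 2.23 and -8.02 to -7.76, and the list calls from 25 to 29. Where 1 Nipponbare library was left, it was assumed to vary like the other groups. The prior without trend gave 12808, 15031 and 7748 changed loci, edgeR 15661, 17644 and 11917, DESeq2 14045, 16040 and 10152, and every transcript model tested 18037, 20277 and 12623.

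The list tests depended most on the correlation assumed, with 28 of 60 called at the preset value, 0 with an estimated correlation (0 also at an unadjusted p under 0.05, the smallest being 0.0649) and 27 by fry. The source of that change was not examined. The correlations were estimated from only 8 libraries, so a lost call does not show that a list was unchanged. By fry 2 lists lost their call between the lines with the direction turned, auxin (adjusted p = 0.817, median beyond that of all loci 0.093, as in camera, with a test of lower values) and grain size (adjusted p = 0.552, 0.3). Because fry tests against no change and camera against the other loci, such a turn is not a contradiction. Over all alternatives, list results were the same 1414 times, lost 59 times, gained 26 times and reversed 2 times. Named genes were the same 5738 times, lost 67 times and reversed once, Os11t0247300-01 at -0.07 under quantile normalization, whose cause was not tested.

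The chromosome 6 log2 odds were -0.105 (Fisher exact p = 0.08) and passed the threshold at -0.119 with a pseudocount of 0.25, -0.139 without a filter, -0.15 under median-ratio scaling, -0.134 under quantile normalization, -0.139 with only the groups compared and -0.131 by edgeR. Without 1 library at a time they ranged from -0.16 (without GW6a-4.6 replicate 2) to -0.059 (without Nipponbare replicate 1). They also passed without Nipponbare replicate 2 (-0.144), without GW6a-4.6 replicate 1 (-0.129) and without OsglHAT1-OE replicate 2 (-0.129), and the cause was not tested. Windows past the threshold for GW6a-4.6 against Nipponbare numbered 6 of 319, 1 of 635 with 50 loci each and 7 of 132 with 250. For OsglHAT1-OE against Nipponbare they numbered 0 of 319, 0 of 635 and 3 of 132. Smaller windows hold fewer loci.

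With the replicate number as a block, the counts were 14698, 16421 and 10908, with 10814 for both lines, 26 list calls and chromosome 6 log2 odds of -0.085. The calls it ended were defence in GW6a-4.6 against Nipponbare (adjusted p = 0.0589) and auxin between the lines (0.0628). Correlations of deviations from the group means were 0.0043 to 0.1 between libraries of the same number and -0.1 to 0.047 between others. OsglHAT1-OE replicate 3 correlated best with GW6a-4.6 replicate 2 (0.047), above its own number in GW6a-4.6 (0.0043). Every other library correlated best with a library of its own number. The main model treated the libraries as sharing only a number. A weak shared source stays possible, as all 7 pairs of the same number were positive and 10 of the 14 others negative, the latter in part because deviations within a group sum to 0. At the depth of these libraries, values under 0.391 to 0.576 rest on fewer than 3 reads.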

Other observations

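The lists of the first 2 paragraphs of this part and their genes were chosen after the data had been seen, so their tests are not independent of it. Desiccation proteins fell in both lines: of 34 LEA, dehydrin and early light-inducible loci, 25 fell and 3 rose in the libraries labelled GW6a-4.6 (25 and 4 adjusted over the list alone, median log2 change -1.36, adjusted p = 3.21e-11, and adjusted p = 0.69 with an estimated correlation). In those labelled OsglHAT1-OE 25 fell and 2 rose (median -1.42, adjusted p = 3.54e-08, and adjusted p = 0.69 with an estimated correlation). The LEA protein Os01t0705200-01, of a family that protects drying cells, fell from 793 ± 29 (n = 2) to 50.3 ± 7.8 and 49.1 ± 9 (n = 3 each). The LEA protein Os01t0314800-01 fell from 411 ± 26 to 49.6 ± 3.9 and 8.59 ± 1.4. Between the lines 9 loci fell and 1 rose (adjusted p = 0.682, with 0.0558 by fry).

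Class III chitinases and glycoside hydrolases of family 18 rose at 17 of 19 loci and fell at 1 in the libraries labelled GW6a-4.6 (median 2.87, adjusted p = 4.04e-10, and adjusted p = 0.69 with an estimated correlation). In those labelled OsglHAT1-OE 6 rose and 6 fell (median 0.07). Many of these loci are neighbouring paralogs on chromosome 11, from Os11t0700900-02 to Os11t0702200-01. They may share reads and are not independent, and they also lie in the chromosome 11 window given above. Sucrose and starch enzymes split: sucrose synthase 2 (Os03t0401300-01) rose from 1550 ± 56 to 5630 ± 320 and 8590 ± 240, while a beta-amylase (Os03t0141200-01) fell from 576 ± 59 to 16.7 ± 4.1 and 16.9 ± 1.5. Of the 36 loci of that list, 14 rose and 9 fell in GW6a-4.6 by label (adjusted p = 0.586, called higher by fry at 0.00285), 12 and 12 in OsglHAT1-OE (adjusted p = 0.459), and 4 rose and 9 fell between the lines (adjusted p = 0.856, called lower by fry at 0.00959). The 26 hAT loci rose 10 and fell 8 times in GW6a-4.6 (adjusted p = 0.19, called higher by fry at 0.000242), and 1 and 4 times in OsglHAT1-OE (adjusted p = 0.859). Between the lines they rose once and fell 10 times (adjusted p = 0.0563, called lower by fry at 0.000138). By camera that list was called in 8 of 18 alternatives, with adjusted p from 0.0166 to 0.178 over them all.

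Among genes of the planned flowering list, GIGANTEA (Os01t0182600-03) fell 1.41-fold from 1950 ± 5.5 to 1380 ± 84 and Hd1 (Os06t0275000-01) fell 4.47-fold to 2.54 ± 1.2 in the libraries labelled GW6a-4.6. Both also fell in those labelled OsglHAT1-OE, to 1410 ± 61 and 3.62 ± 0.23. Neither differed between the lines by limma (adjusted p = 0.731 and 0.204). In the planned meristem list, DROOPING LEAF (Os03t0215200-00), which specifies the carpel, rose from 6.24 ± 0.96 to 19.4 ± 2.9 and 22.3 ± 4.3. The grain width gene GS5 (Os05t0158500-01), chosen after its values were seen, was at 17.2 ± 2.8 in Nipponbare, 42 ± 3.1 in GW6a-4.6 and 51.3 ± 3.8 in OsglHAT1-OE by label.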
